A study of Mus musculus with 2 samples.

How the data were processed

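Total RNA was sequenced from CH12.LX, a mouse B cell lymphoma line, in 2 libraries that the labels name biological replicates 1 and 2 of a single group. Each replicate has its own biosample record, and nothing in the labels says more of how the cultures were grown. There was therefore no contrast between conditions, and the only comparison between samples was library against library.

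Each library had gene-level tables made with annotation releases M2, M3 and M4 and a transcript-level table made with M4, all on assembly mm10, per the labels and the manifest of each library. The aligner, the quantifier and their versions are not given in the sources used here. The deposited expected counts are estimated counts per gene or transcript, per the file headers, and their values were not all whole. The deposited TPM values, named so per the file headers, summed to 999998 in replicate 1 and 999999 in replicate 2 over the genes used. The deposited FPKM values and posterior mean TPM values, per the file headers, were used only in alternatives. The deposited percent values in the transcript tables give the share of a transcript in its gene, per the file headers. The authors also deposited other columns, the lower and upper credibility bounds of TPM, per the file headers.

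The M4 gene table was taken as the main one, because its gene identifiers match the transcript table, by a rule set before the data were examined. It has 69691 rows, of which 43346 carry an Ensembl gene identifier. Another 26248 rows have numeric identifiers that name no gene. They held 28 expected counts in replicate 1 and 29.99 in replicate 2, or 5.68e-05% and 5.36e-05% of the total. The remaining 97 rows name spike-in sequences and held 0 counts. Both kinds of row were left out. Gene symbols, biotypes and coordinates came from GENCODE M21 on the same assembly, matched on the identifier without its version, and 42462 of the 43346 genes matched. Coordinates are those of M21. Library totals were 49278383 expected counts in replicate 1 and 55950529 in replicate 2.

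Levels are given as TPM, as the mean ± SD over the 2 libraries. A gene was called detected at 1 TPM or more in each library. Expected counts were rounded to whole numbers for count-based steps. Scaling used TMM factors from edgeR 4.0.16 in R 4.3.3, computed over genes with at least 10 rounded counts summed over the libraries. Genes were compared between the libraries with a two-sided exact conditional binomial test, in which the smaller tail was doubled, with Benjamini-Hochberg adjustment at 0.05 and a ratio of at least 2. This test covers counting error only and compares these libraries, not conditions. It does not cover the assignment of shared reads, so the deposited credibility bounds of called genes were also compared between the libraries, a step added after the values were seen. edgeR's common dispersion was estimated from an intercept-only fit. Other steps ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.

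The 38 gene lists were fixed together with the rule for the main table. Faim3 was matched to its current symbol Fcmr. The members H2-Ea, Snhg1, Ighg2a, Iglc1, Iglc3 and Iglc4 had no match and were not analysed here. Ighd matched the pattern of the variable gene list but is the constant delta gene, so it was left out of that list, which departs from the pattern as fixed. The median of the mean TPM of a list was set against 10000 random lists of the same size from protein-coding genes. For the comparison of libraries, the median log2 ratio of TPM with a pseudocount of 0.1 over members at a mean of 1 TPM or more was set against 10000 random lists matched on mean expression in 20 bins. Random lists were drawn with replacement. Lists with fewer than 5 such members were not compared, a minimum set after the data were seen, which left 30 lists. A median past the 97.5th percentile or below the 2.5th was called outside the central range. These percentiles describe the 2 libraries and are not p-values, since genes are not replicates.

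The rule for the genes named in the text was fixed together with the lists. It takes up to 4 members with the highest and 4 with the lowest mean TPM per list, the 20 nuclear protein-coding genes with the highest mean TPM, and the 10 genes per direction with the largest ratio between libraries past the binomial test at a mean of 1 TPM or more. It also takes all immunoglobulin constant genes, the 5 highest variable genes per chain, and transcripts with at least 10% of a listed gene in both libraries. Some genes that the rule takes are not reported here. Genes named outside this rule were chosen after their values were seen.

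The binomial test was tested on counts simulated for replicate 2 against replicate 1, from the gene means over both libraries and their effective library sizes. With no variation beyond counting and 15435 genes tested, it called 0% of genes simulated at a 1.5-fold difference, which lies under the ratio of 2. It called 100% of genes simulated at a 3-fold, 4-fold or 8-fold difference and 0.0131% of unchanged genes. With a biological coefficient of variation of 0.1 and 15389 genes tested, it called 4% of genes at a 1.5-fold difference, 100% at each of the larger folds and 0.527% of unchanged genes. Folds were simulated only in genes with at least 100 expected counts over both libraries, so these rates do not cover genes with fewer counts. The coefficient estimated from the libraries was 0.180, a level that was not simulated, so more unchanged genes may be called in these data. Intervals of ratios are 95% intervals from counting error, and the floor for a count of 0 is 3 counts. Amplified reads are not independent molecules, so both cover counting error only. Alternatives covered thresholds, pseudocounts, scaling with DESeq2 1.42.0 size factors, filters, units, annotation releases and leaving out each replicate. Pearson's r and Spearman's rho were counted as moved when they left 0.01 of the main value, a tolerance set after the data were seen.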

Results

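CH12.LX is an established mouse B cell lymphoma line that is widely used as a model of antibody class switching. Total RNA from the line was profiled in 2 libraries, biological replicates 1 and 2 of a single group. The tables held 49278383 expected counts for replicate 1 and 55950529 for replicate 2. Of 43346 genes listed, 9571 reached 1 TPM in both libraries, and 8895 of these were protein-coding. Protein-coding genes held only 24.3% of TPM. Their levels therefore read lower, and the 1 TPM threshold is stricter, than on a scale of protein-coding genes alone. More genes reached 1 TPM in both libraries when TPM was rescaled to protein-coding genes. The design holds no contrast, so levels are described and the replicates are compared with each other.

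The RNA profile was dominated by abundant short noncoding RNAs when counted in TPM. Small noncoding classes held 69.7% ± 0.938 of TPM (SD, n = 2) but 13.4% ± 0.219 of expected counts. Protein-coding genes held 24.3% ± 0.0964 of TPM and 70.5% ± 2.10 of expected counts. Rn7s1 was at 133814 TPM in replicate 1 and 148497 TPM in replicate 2, and Rn7s2 at 134547 and 151000 TPM. Below these, Rn7sk, the 7SK RNA that restrains transcription elongation, was at 61803 ± 6900 TPM (chromosome 9, 78175303 to 78175633). Rmrp, the RNA of RNase MRP, was at 39524 ± 4200 TPM, and Rpph1, the RNA of RNase P, was at 16817 TPM in replicate 1 and 8590 TPM in replicate 2. The 10 highest genes took 51.0% ± 3.91 of TPM and the 100 highest took 78.7% ± 0.642. Among protein-coding genes alone, the 10 highest took 8.52% ± 1.24.

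**Figure D1:**
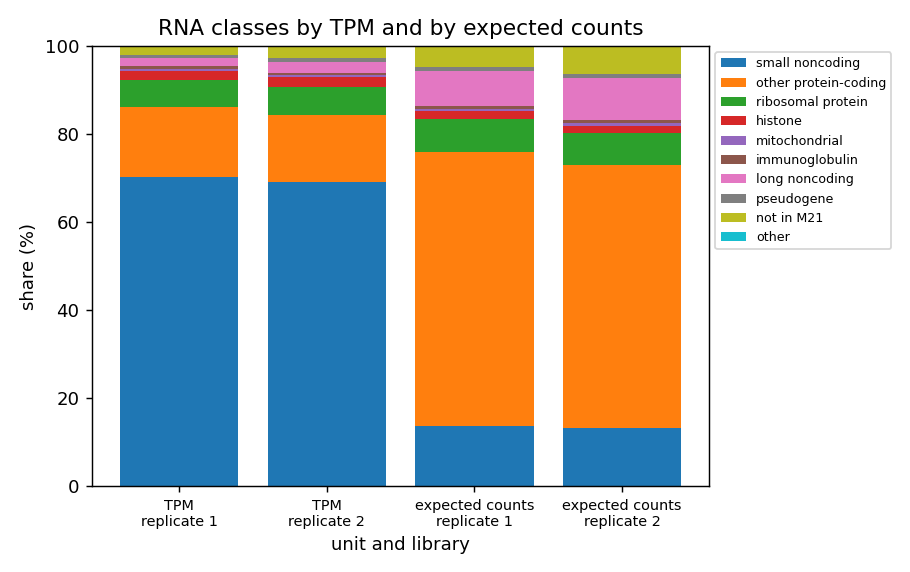
Stacked bars give the share in percent of each RNA class in each of the 2 libraries, by TPM and by expected counts. Small noncoding RNA held 69.7% of TPM but 13.4% of expected counts, as means of the libraries.

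The 20 highest nuclear protein-coding genes included many of ribosomal proteins. Eef1a1, the translation elongation factor, was at 3627 ± 484 TPM (chromosome 9, 78478449 to 78489151) and Rplp1, a ribosomal stalk protein, at 3159 ± 247 TPM. Rpl41, Rpl26, Rps12, Rpl13a, Rps2, Rpl38, Rps29, Rplp0 and Rpl32 were also among the 20 highest, with Rack1 at 1394 ± 110 TPM, Actb at 1256 ± 25.7 TPM and Ppia at 2266 ± 261 TPM. Of 82 cytosolic ribosomal protein genes, 79 were detected. Replication-dependent histones were also abundant, with 58 of 68 detected and a median of 241 TPM. Hist1h4d was at 1719 ± 214 TPM and Hist1h4n at 1231 ± 57.2 TPM. Histone genes have near-identical copies, so single-gene values are uncertain. Lars2, the mitochondrial leucyl tRNA synthetase, was also among the 20 highest, at 991 TPM in replicate 1 and 3641 TPM in replicate 2. Whether all reads assigned to Lars2 come from its own mRNA was not tested, so its value is uncertain.

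B cell identity genes were expressed and markers of other lineages were largely not. Of 20 B cell identity genes, 17 were detected and 11 reached 10 TPM in both libraries. The median of the list, 11.7 TPM, was at the 100th percentile of random protein-coding lists. Cd79b, a signalling chain of the B cell receptor, was at 123 ± 3.16 TPM, Ly86 at 55.9 ± 13.8 TPM, Ralgps2 at 38.3 ± 4.67 TPM and Spib, a lymphoid transcription factor, at 36.3 ± 9.89 TPM. At the low end Cr2, the complement receptor of mature and marginal zone B cells, was at 0.04 TPM in replicate 1 and 0.02 TPM in replicate 2. All 20 B cell receptor signalling genes were detected, with Ptpn6 at 63.7 ± 6.62 TPM, Prkcb at 54.9 ± 8.05 TPM and Plcg2 at 47.9 ± 2.05 TPM. Of 24 lymphoid transcription factors, 20 were detected. Tcf3 was the highest, at 42.1 TPM in replicate 1 and 47.9 TPM in replicate 2, with Xbp1 at 31.4 ± 6.37 TPM and Irf4 at 30.1 ± 4.04 TPM. Bcl6, Bach2, Klf2 and Foxo1 were the 4 lowest, and Bcl6, the germinal centre repressor, was at 0.04 TPM in replicate 1 and 0.06 TPM in replicate 2.

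Genes of B cell stages were expressed to different extents. Of 14 plasma cell genes, 12 were detected, led by Mzb1, a chaperone of antibody secretion, at 201 ± 19.0 TPM and Jchain, the joining chain of secreted IgM and IgA, at 145 ± 43.5 TPM. Prdm1, the plasma cell repressor, was at 2.29 ± 0.495 TPM. Of 12 germinal centre genes, 6 were detected, led by Mef2b at 51.2 ± 6.10 TPM and Rgs13 at 37.9 ± 3.46 TPM. Of 28 class switching and hypermutation genes, 27 were detected. Of 16 B-1 and marginal zone genes, 10 were detected, with Plscr1 at 48.5 TPM in replicate 1 and 92.8 TPM in replicate 2 and Zbtb32 at 43.4 ± 0.537 TPM. Cd5, a marker of B-1 cells, was at 2.10 ± 0.177 TPM. Only Lef1, at 3.25 ± 0.0354 TPM, was detected among 12 early precursor genes. Rag1, a recombinase subunit, had 0 counts, a floor of 0.00421 TPM in replicate 1 and 0.00386 TPM in replicate 2.

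Of 83 markers of 7 other cell type lists, 11 were detected and 61 were under 0.1 TPM in both libraries. More of these markers reached 1 TPM when TPM was rescaled to protein-coding genes, while the number of B cell identity genes detected stayed the same. The detected markers included Cd68 at 18.1 ± 0.679 TPM, Lck, a kinase of T cell receptor signalling, at 17.9 ± 2.39 TPM, Batf3 at 10.7 ± 1.90 TPM, Adgre1 at 5.50 ± 1.24 TPM, Pecam1 at 4.64 and 5.35 TPM in replicates 1 and 2, and Epcam at 1.86 ± 1.22 TPM. By list, 5 of 17 T cell, 0 of 10 NK cell, 2 of 14 myeloid, 2 of 9 dendritic cell, 0 of 11 erythroid and megakaryocyte, 1 of 12 stroma and endothelium and 1 of 10 epithelium and liver markers were detected in both libraries. Hba-a1 and Hba-a2, alpha globin genes with near-identical sequence and so uncertain, reached 1 TPM in replicate 2 alone, at 1.19 and 1.07 TPM.

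**Figure D2:**
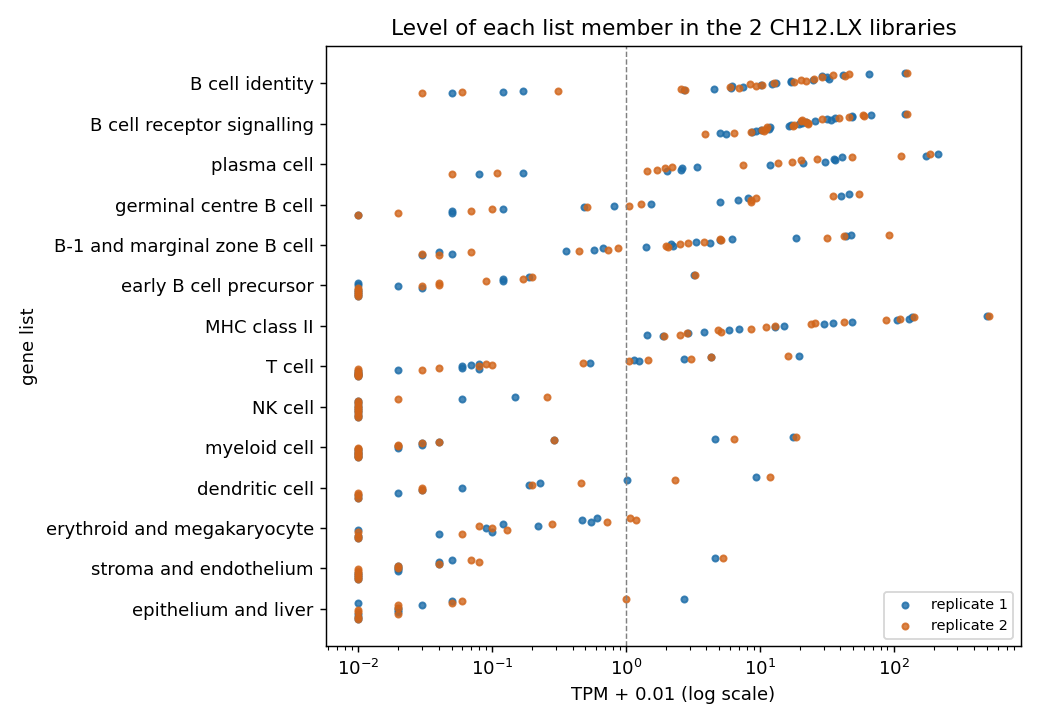
Each point is a member of a gene list in a library, placed by TPM plus 0.01 on a log axis, with the lists as rows and the dashed line at 1 TPM. In the B cell identity list 17 of 20 members lie above that line in both libraries, while in the pooled lists of 7 other cell types 11 of 83 do.

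Immunoglobulin expression was nearly restricted to a single heavy and a single light variable gene. Ighv1-53 (chromosome 12, 115158403 to 115158835) was at 1563 ± 47.2 TPM and held 99.9% of heavy variable TPM. Igkv10-96 (chromosome 6, 68631963 to 68632442) was at 1160 ± 104 TPM and held 98.6% ± 0.184 of light variable TPM. The next highest were Igkv14-111 at 8.99 ± 1.85 TPM, Iglv3 at 3.87 ± 0.0919 TPM and Iglv1 at 1.96 ± 0.361 TPM. Among constant genes, Ighm was at 1498 ± 66.3 TPM, 88.4% ± 0.292 of heavy constant TPM, and Igha at 193 ± 13.7 TPM, 11.4% ± 0.269. Ighg3 was at 1.70 ± 0.177 TPM, Ighg1 at 0.995 ± 0.163 TPM, Ighg2b at 0.710 ± 0.382 TPM, Ighd at 0.255 ± 0.134 TPM, Ighe at 0.170 ± 0.0566 TPM and Ighg2c at 0.0800 ± 0.0566 TPM. Igkc was at 1506 ± 16.6 TPM, 88.1% ± 0.956 of light constant TPM, and Iglc2 at 203 ± 20.8 TPM. The light constant share of Igkc was 72.9% by expected counts. Iglc2 belongs to a family of closely related genes, so its value is uncertain.

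**Figure D3:**
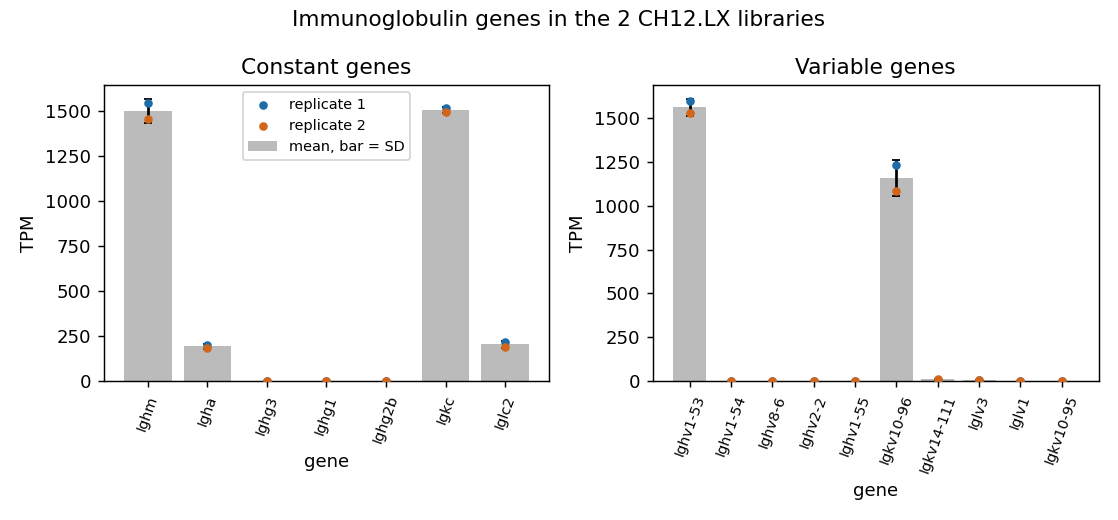
Bars give mean TPM over the 2 libraries with the SD, and points give each library, for the 5 highest genes of each immunoglobulin class. Ighm and Igkc lead the constant genes at 1498 and 1506 TPM, and Ighv1-53 and Igkv10-96 lead the variable genes at 1563 and 1160 TPM.

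Transcript tables gave the form of the mu chain. Ighm-201, a transcript of 4 exons that ends before the membrane exons, held 71.8% ± 2.67 of Ighm TPM. Ighm-202, a transcript of 6 exons that reaches 113418558 on chromosome 12, held 28.2% ± 2.67. Pkm-201 held 92.5% ± 0.311 of Pkm, Cd79b-202 held 89.8% ± 0.735 of Cd79b and Cd44-203 held 70.4% ± 2.89 of Cd44. Ikzf1-201 and Ikzf1-204 held 45.7% ± 2.73 and 50.5% ± 2.63 of Ikzf1 by TPM, but 19.7% and 78.8% by expected counts, as means of the libraries. Mcl1-201 held 92.4% of Mcl1 in replicate 1 and 75.7% in replicate 2. Short reads split transcripts of a gene indirectly, so these shares are estimates.

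Antigen presentation genes were expressed throughout. All 15 matched MHC class II genes were detected, with Cd74, the invariant chain, at 506 ± 14.5 TPM, H2-Eb1 at 140 ± 3.92 TPM, H2-Ea-ps at 131 and 111 TPM in replicates 1 and 2, and H2-Aa at 96.5 ± 12.4 TPM. All 12 MHC class I genes reached 10 TPM, with B2m at 358 ± 2.89 TPM. All 17 NF-kB genes were detected, with Nfkbia, the inhibitor of NF-kB, at 137 ± 38.0 TPM and Nfkb1 at 59.9 ± 2.19 TPM. Of 25 cytokines, 9 were detected, led by Ccl22, a chemokine, at 397 TPM in replicate 1 and 744 TPM in replicate 2 and by Il10 at 94.6 ± 2.41 TPM. Of 23 cytokine and chemokine receptors, 15 were detected, with Tnfrsf13b at 75.9 ± 18.0 TPM, Tnfrsf13c, the receptor for the B cell survival factor BAFF, at 52.4 ± 8.93 TPM and Ccr7 at 49.3 ± 11.9 TPM. Of 19 Toll-like receptor pathway genes, 10 were detected, and Tlr3, Tlr5, Tlr8 and Tlr11 were under 0.1 TPM in both libraries.

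Proliferation genes were high. All 20 S phase genes and all 20 G2 and M phase genes were detected, with Pcna at 98.3 ± 19.6 TPM, Mcm6 at 66.7 ± 4.97 TPM, Top2a at 98.7 ± 3.17 TPM and Cdk1 at 64.7 ± 8.76 TPM. Cdk4 was at 82.3 ± 4.92 TPM and Ccnd2 at 26.9 ± 3.37 TPM. Cdkn2a and Cdkn2b, neighbouring cell cycle inhibitor genes on chromosome 4, both had 0 counts in both libraries. The floors were 0.0380 and 0.0351 TPM for Cdkn2a and 0.0220 and 0.0202 TPM for Cdkn2b in replicates 1 and 2. All 20 apoptosis genes were detected, with Bcl2a1b, an anti-apoptotic BCL2 relative, at 95.5 ± 46.3 TPM. Bcl2a1b has near-identical copies, so its value is uncertain. Npm1, a nucleolar protein, was at 944 ± 51.1 TPM and Myc at 15.1 ± 0.594 TPM, and 13 of 16 MYC and ribosome biogenesis genes were detected. Of the other lists, 11 of 15 D cyclins and cell cycle inhibitors, 14 of 14 chromatin regulators, 5 of 14 interferon response, 10 of 16 immediate early and stress, 14 of 16 glycolysis and hypoxia, 11 of 15 noncoding RNA, 15 of 37 mitochondrial genome and 12 of 12 housekeeping genes were detected. Of 6 Y chromosome genes, 4 were detected in these libraries labelled female, with Eif2s3y at 10.7 ± 0.728 TPM, Ddx3y at 5.41 ± 0.615 TPM, Kdm5d at 3.87 ± 0.339 TPM and Uty at 2.54 ± 0.198 TPM. This holds with M4 alone, since M2 and M3 list every Y-linked gene at 0 counts, 173 and 1362 genes, with upper credibility bounds of 0 in both libraries. Xist, the RNA of the inactive X chromosome, was listed at 0 TPM in both libraries, with 0 and 2 expected counts.

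The replicates were similar across genes but differed by far more than sampling noise. Pearson's r of log2(TPM + 1) was 0.988 across 43346 genes and Spearman's rho was 0.943, and the SD of the difference was 0.24 on the log2 scale. Genes are not independent replicates, so no p is given. The chi-square per degree of freedom was 172 over 15438 genes, so the libraries differed by more than sampling noise and were counted as 2 samples. The common biological coefficient of variation was 0.180.

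The glycolysis and hypoxia list and the immediate early and stress list were higher in replicate 2 than in replicate 1, and the plasma cell, S phase and MYC and ribosome biogenesis lists were lower. The erythroid and megakaryocyte list had too few members at a mean of 1 TPM to be compared in the main setting. In the alternative at a mean of 0.1 TPM or more, 4 of its 5 members were higher in replicate 2. Their median log2 ratio was 0.74, at the 99.5th percentile. This rests on few genes at low levels, including the near-identical Hba-a1 and Hba-a2, so it is uncertain. Gm42418, singled out after its values were seen, was at 4866 and 13744 TPM in replicates 1 and 2, and Lars2 at 991 and 3641 TPM. With 1 library on each side, these differences have no replicate check. All 14 glycolysis and hypoxia genes at 1 TPM or more were higher in replicate 2, with a median log2 ratio of 0.76 against a central range of -0.26 to 0.08 in matched random lists. Aldoa, a glycolytic enzyme, was at 281 TPM in replicate 1 and 551 TPM in replicate 2, Gapdh at 520 and 736 TPM, and Bnip3, a mitophagy receptor induced by hypoxia, at 6.72 and 25.5 TPM. In the immediate early and stress list, 8 of 10 members were higher in replicate 2, with a median of 0.55. Ddit3, the stress factor CHOP, was at 5.52 TPM in replicate 1 and 25.4 TPM in replicate 2, and Trib3 at 3.98 and 13.6 TPM, while Hsp90aa1 was at 255 and 172 TPM. NF-kB genes had a median of 0.32, with 12 of 17 higher in replicate 2, cytokines a median of 0.36 and apoptosis genes a median of 0.19. The other lists above the central range were D cyclins and cell cycle inhibitors at 0.16, noncoding RNA at 0.14, lymphoid transcription factors at 0.13, histones at 0.06 and ribosomal proteins at 0.01. Of these lists, lymphoid transcription factors (median -0.09), D cyclins and ribosomal proteins lay inside the range at a mean of 10 TPM or more, noncoding RNA with TMM-scaled counts and apoptosis with M2. The median over all genes at a mean of 1 TPM or more was -0.04.

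Among plasma cell genes, 11 of 12 were lower in replicate 2, with a median log2 ratio of -0.58. Jchain was at 176 TPM in replicate 1 and 114 TPM in replicate 2, and Fkbp11, an endoplasmic reticulum prolyl isomerase, was at 30.6 and 17.3 TPM. All 20 S phase genes were lower, with a median of -0.33, and Pcna was at 112 and 84.5 TPM. Of 20 G2 and M phase genes, 19 were lower, but their median of -0.17 lay inside the central range. MYC and ribosome biogenesis genes had a median of -0.36, with 11 of 13 lower. Mitochondrial genome genes had a median of -0.53, with 12 of 15 lower, but with the M2 annotation the median was -0.16, inside the central range. In all, 14 of 30 lists lay outside their central range. Genes of a list can vary together, so this number has no chance level here. B cell identity, at -0.05, and housekeeping genes, at -0.06, lay inside it.

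**Figure D4:**
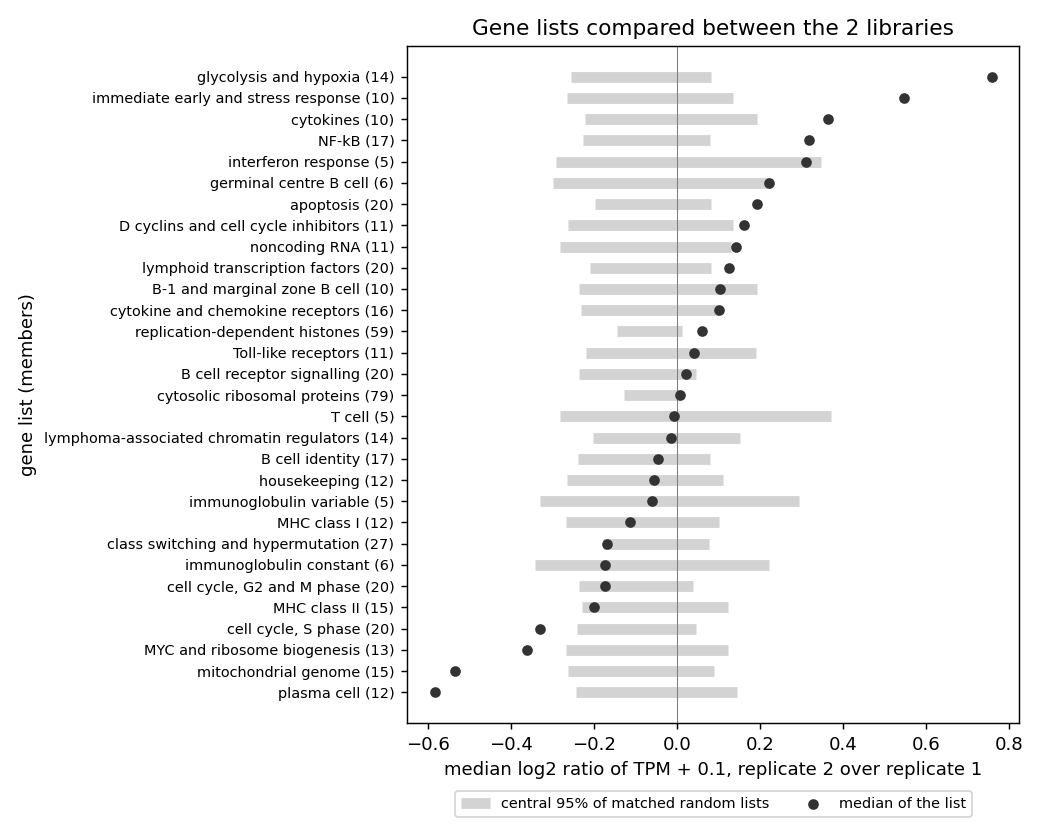
Points give the median log2 ratio of TPM + 0.1 in replicate 2 over replicate 1 for each of 30 gene lists, with the number of members in brackets, and grey bars give the central 95% of matched random lists. Glycolysis and hypoxia lies highest at 0.76 and plasma cell lowest at -0.58.

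The exact binomial test called 726 of 15438 genes different between the libraries, 563 higher and 163 lower in replicate 2. Without the ratio criterion the split was nearly even, with 3898 of 7779 called genes higher and 3881 lower in replicate 2. Of the 726 genes, the rest of this paragraph gives subsets. Among the 726 genes, 142 had a mean of 1 TPM or more, and 101 of those were protein-coding, 92 higher and 9 lower in replicate 2. The deposited credibility bounds of TPM of the libraries overlapped for 315 of the 726 genes, and for 12 of the 142. By list, 4 immediate early and stress genes (Ddit3, Trib3, Atf3 and Chac1), 3 glycolysis and hypoxia genes (Bnip3, Pdk1 and Vegfa), 3 histones, 2 dendritic cell markers (Zbtb46 and Xcr1), 2 erythroid and megakaryocyte markers (Hba-a1 and Epor), the stroma and endothelium marker Cdh5, Id3, Il6, Bcl2a1b, Irf7 and Ighd were called higher, and 3 mitochondrial genes (mt-Co2, mt-Nd3 and mt-Atp8), Epcam, Mx1 and Rpph1 lower. Of these other lineage markers, Xcr1, Hba-a1 and Epor had means of 0.335, 0.825 and 0.190 TPM, and Cdh5 was at 0.03 TPM in replicate 1 and 0.07 TPM in replicate 2. The test called 0 B cell identity, 0 plasma cell and 0 S phase genes. The log2 ratio of Ddit3 was 2.24 (95% counting interval 2.09 to 2.39), that of the glycolytic gene Aldoc 1.89 (1.80 to 1.99), that of Bnip3 1.87 (1.77 to 1.98) and that of the cytokine gene Il6 1.93 (1.56 to 2.30). Lars2 and Saxo2 were also among the 10 genes with the largest ratio, both at 1.90. The source of the reads assigned to Lars2 was not tested, so its ratio need not reflect its own mRNA. Gm14296 was at 2.19 by counts, but its TPM was 0.96 and 2.24 with overlapping bounds, 1.13 to 2.98 in replicate 1 and 1.53 to 2.86 in replicate 2. Gm15433, Gm10359 and Gm8129, the processed pseudogenes among them, can share reads with their parent genes and are uncertain. Toward replicate 1, mt-Nd3 had a log2 ratio of -1.52 (-1.59 to -1.45) and 1700120C14Rik -2.10. The ratios of mt-Co2, at -2.55, and 2210418O10Rik, at -2.17, are unresolved, since their bounds overlapped. For mt-Co2 the bounds were 92.2 to 561 TPM in replicate 1 and 4.76 to 325 TPM in replicate 2, which do not hold its listed 26.4 and 4.48 TPM. The pseudogene Gm12671 had 1109 expected counts in replicate 1 and 0.85 in replicate 2, but its bounds, 6.59 to 30.4 TPM and 1.18 to 66.2 TPM, overlapped, so its difference is unresolved too. With edgeR's exact test at an assumed biological coefficient of variation of 0.2, close to the estimate, 69 genes were called.

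The gene-level tables agreed closely across annotation releases for most genes, though not in their totals. With M2 the totals were 44833279 and 50569795 expected counts in replicates 1 and 2, against 49278383 and 55950529 with M4. Pearson's r of log2(TPM + 1) between M4 and M2 was 0.995 in both libraries, over 38253 shared genes, and that between M4 and M3 was 0.999 in replicate 1 and 0.998 in replicate 2. Between M4 and M2, 124 genes at 1 TPM or more in either table differed at least 2-fold in replicate 1 and 118 in replicate 2. Between M4 and M3, the numbers were 39 and 37. Gm26917, a long noncoding gene on chromosome 17 singled out after its values were seen, had 2576760 expected counts with M4 and 495400 with M2 in replicate 1. ENSMUSG00000045999, singled out in the same way, had 1848120 expected counts with M4 and 9030 with M2 in replicate 1.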

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

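The test that left out 5 abundant RNAs was chosen only after the result was seen. The test on genes under 200 nt was added only after the full-length test on protein-coding genes had ended between its bounds, though before its own value was seen. Features that name no gene held 28 expected counts in replicate 1 and 29.99 in replicate 2, summed over 26248 rows. The 3 counts that a count of 0 allows apply to a single feature, so these sums are not read as a signal. A signal did lie outside the TPM column. Genes with more than 3 expected counts but a TPM of 0 numbered 73 in replicate 1 and 91 in replicate 2. Snora52, a small nucleolar RNA of 137 nt, had 927 expected counts and 8010 TPM in replicate 1 against 999.7 counts and 0 TPM in replicate 2. Its effective length was 1.05 in replicate 1 and 0 in replicate 2.

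Genes under 200 nt held 23.7% ± 3.49 of TPM but 0.512% ± 0.180 of expected counts. When counts were divided by full length in place of effective length, their share was 2.91%. That fall was largely set by the divisor, so it tests no explanation. Full length was at least 4.95 times effective length for each of these genes with counts and an effective length above 0 in replicate 1. For the small share of protein-coding genes, the same change raised it from 24.3% to 43.4%, between the bounds of 40% and 50% set before this value was seen, so how far effective lengths account for it stays open. Leaving out Rn7s1, Rn7s2, Rn7sk, Rmrp and Rpph1 raised the share to 40.5%, under the 50% that these RNAs as the whole cause would need. No biological explanation was tested, since the design has a single group.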

How the results depend on the processing

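The alternatives with TPM rescaled to protein-coding genes, and those with protein-coding genes only for replicate agreement and differing genes, were chosen after seeing the data. The median of lymphoid transcription factors, called above its range, turned negative at a mean of 10 TPM, at the 59.6th percentile. Medians of 4 lists inside their range also changed sign under an alternative: B cell receptor signalling, Toll-like receptors, T cell and chromatin regulators. Y-linked genes detected numbered 4 with M4, 1 at 10 TPM and 0 with M2 and with M3. Counts of genes were taken as moved past 1.5 times the main count, r and rho past 0.01, and shares past 1 SD between the libraries. By these unequal tolerances, 116 alternatives to the main results stayed and 34 moved. The 116 include the runs that left out a replicate, and rho at other pseudocounts, which cannot change ranks. Detected genes stayed by this measure but numbered 13077 at 0.1 TPM and 13745 at 10 rounded counts. They also rose, within the tolerance, with TPM rescaled to protein-coding genes. The cause was not tested unless the alternative itself gives it. No paired analysis was possible because there is a single group. With 2 libraries, leaving out either moves a mean by less than its SD by construction, so the ranges say nothing about stability. Detected genes ranged from 9744 to 9900 that way, and other cell type markers from 11 to 13.

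At 10 TPM, fewer genes pass by construction: 3362 genes, 11 B cell identity genes, 2 other cell type markers, and means of 77.5 and 21.5 genes that differed 2-fold between M4 and M2 or M3. At 0.1 TPM, 20 other cell type markers passed, and 7 passed with the lower credibility bound.

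With expected counts, the 10, 100 and 1000 highest genes held 28.2%, 42.1% and 67.1%. Protein-coding and small noncoding genes then held 70.5% and 13.4%, Ighm 90.6% of heavy constant, Igkc 72.9% of light constant, and Ighm-201 and Ighm-202 68.8% and 31.2% of Ighm. Among protein-coding genes only, the top shares were 8.52%, 38.8% and 72.5% and Spearman's rho was 0.979. At a mean of 1 TPM or more, Pearson's r was 0.963 and rho 0.970.

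With M2 and M3, the Ighm share was 88.8% with each, the protein-coding share 24.6% and 24.9%, and the small noncoding share 71.5% and 71.4%. Without mitochondrial genes the protein-coding share was 24.1%.

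Genes that differed between libraries numbered 283 at 100 or more counts, 1681 at a ratio of 1.5, 7779 without a ratio criterion, and 445 and 69 with edgeR's exact test at assumed biological coefficients of variation of 0.1 and 0.2. Of 203 comparisons of single list differences, 189 kept their side of the central range, 7 left it, 6 entered it and the 1 above turned. With total count scaling, 67.7% of 665 differing genes were higher in replicate 2, with 77.5% in the main test. Depth limits genes with few counts, whose ratios have wide counting intervals. Mitochondrial genes entered the range with M2 and M3, at the 16.5th and 17.0th percentile.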

Other observations

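The tests on other cell types and on the label of sex, and the comparison of releases for Y-linked genes, were chosen only after the result was seen. Some genes fell outside the named gene rule and were chosen after their values were seen. Pck2, a mitochondrial carboxykinase, was at 17.1 TPM in replicate 1 and 47.6 TPM in replicate 2 and Pycr1, an enzyme of proline synthesis, at 6.52 and 19.4 TPM. Asns, asparagine synthetase, had 1 and 2 expected counts, and Atf4, a stress response factor, was at 83.2 and 115 TPM. The hypoxia genes Ddit4 and Ankrd37 were at 8.57 and 5.87 TPM in replicate 1 and at 25.4 and 17.1 TPM in replicate 2. In the other direction the endoplasmic reticulum factor Manf was at 97.0 and 47.1 TPM and the surface protein Cd24a at 213 and 110.4 TPM.

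Gm42418, on chromosome 17 from 39846958 to 39848788, was at 4866 TPM in replicate 1 and 13744 TPM in replicate 2, while its neighbour Gm26917 was at 8915 and 6664 TPM. Lars2 was at 991 and 3641 TPM, and ENSMUSG00000045999, which has no symbol in the annotation used, was at 14609 and 22370 TPM with M4 but 151 and 99.7 TPM with M2. Iglc2 was at 203 TPM, while the lambda variable genes Iglv3, Iglv1 and Iglv2 were at 3.87, 1.96 and 0.345 TPM. H2-Ea-ps, annotated as a pseudogene in the reference, was at 121 TPM.

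The glycolysis and hypoxia list was higher in replicate 2, with a median log2 ratio of 0.76 in TPM. A shift of TPM shares by abundant noncoding RNA moves all genes alike, so it cannot set a list apart from random lists. With TMM-scaled counts the list median was 0.76, with -0.03 over all genes and an upper bound of 0.08 in random lists. Scaling is itself nearly a factor common to all genes, so this test could not decide. In TPM the median over all genes was -0.04 against 0.76 for the list. A shift common to all genes would not part them, which argues against that shift. After the trend of the ratio on GC content and gene length was removed, the median was 0.76 against an upper bound of 0.10, which argues against such a bias as the whole cause. A difference in culture conditions, such as oxygen or cell density, stays open, and no biological explanation was tested.

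Y-linked genes were detected in libraries labelled female with M4 alone, while M2 and M3 list all 173 and 1362 Y-linked genes at 0 counts with upper credibility bounds of 0 in both libraries. With M2, 74.5% of the other genes at 0 counts in replicate 1 had an upper bound above 0, so M2 and M3 are not read as measuring Y-linked genes, and why these are at 0 was not tested. Reads shared with X-linked homologues are argued against by lower bounds of at least 93.9% of TPM over 4 genes and 2 libraries, and in replicate 1 the 4 homologues had 112 more counts with M2 than with M4, where the 4 Y-linked genes had 7158. The median of 0.015 TPM over the pooled markers of 7 other cell type lists cannot decide on male cells of another type. Cells of 1 type would raise only the markers of their own list, a minority of the pool. That explanation stays open, and types outside those lists were not tested. With M4, in 2 of 2 libraries the 4 Y-linked genes reached 1 TPM and Xist was under 0.1 TPM. This is what a wrong sex in the label would give, an explanation found from these same values. Ighv1-53 held 99.9% of heavy variable TPM and Igkv10-96 held 98.6% of light variable TPM, as means of the libraries. That argues against a large share of B cells with other expressed variable genes. A small share of male B lineage cells, or male cells with these same variable genes or none expressed, stay open.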
